A study of Homo sapiens with 4 samples.

How the data were processed

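Expression was measured on 4 Affymetrix U133 Plus 2.0 arrays of the human embryonic stem cell line H14, hybridised with biotin-labelled material from total RNA per the labels. The groups were hsr positive (2 arrays) and hsr negative (2 arrays), taken from the sample titles together with the replicate number. The deposited values are linear signal intensities of probe sets, made with MAS5 per the submitters' processing notes. The MAS5 version, scaling target and detection calls are not given in the sources used here. From the values, the authors' scaling gave each array a mean intensity of 100.01 after leaving out the lowest and highest 2% of probe sets, so no further scaling between arrays was applied. The number of arrays limits the precision.

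The values covered 54675 probe sets, of which 62 were controls. In the platform annotation 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none, and 41043 of those with 1 symbol matched the reference gene table by Entrez identifier. The reference table (GRCh38.p14) was used for names and gene order only, since the values name no genome build, and no coordinates are given. XIST and genes of the Y chromosome and the pseudoautosomal regions were left out (59 probe sets). Probe sets with a mean over the 4 arrays below the median of all probe sets (24.575) were left out, and each gene took its probe set with the highest mean, which gave 12334 genes.

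Values were analysed as log2(signal + 16), so a fold change is on that scale and understates the change of dim genes. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), hsr positive against hsr negative, two-sided, with Benjamini-Hochberg adjustment at 0.05. The 29 gene lists and 23 chromosomes were tested on the same fit with camera of limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over lists or over chromosomes. The same tests were repeated with an estimated correlation, where camera has only the 2 residual degrees of freedom of the fit. Hardly any set could pass adjustment there, so a call lost in that test says little for or against the set. Of the lists, 13 were called with the preset correlation and 0 with an estimated correlation. Neighbouring genes were compared by the median log2 difference of every 15 measured genes next to each other on a chromosome, with 1000 shuffles of genes over positions for a family-wise permutation p, and windows beyond the 95th percentile of the shuffles' largest absolute window (0.87) were merged into runs. The tables held no chromosome arms, so whole chromosomes were tested. Where a list's median is given within a replicate number, it is the median of the differences between the hsr positive and hsr negative arrays of that number. Percentiles of list medians came from 10000 random lists of the same size matched on mean expression in 20 bins. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

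The lists, fixed before the data were examined as were the tests and most alternatives, covered pluripotency, neuroectoderm, mesoderm, endoderm and yolk sac, trophoblast, fibroblast and feeder-like, germ cell, apoptosis, p53 target, 20q11.21, 12p, 17q, amplicon oncogene, G1/S, G2/M, ribosomal protein, glycolysis, oxidative phosphorylation, hypoxia, heat shock and unfolded protein, immediate early, nodal and TGF-beta, BMP, WNT, FGF and ERK, imprinted, methylation enzyme, DNA repair and cell adhesion genes. Genes named in the text were the 12 with the largest rise and fall among those past the threshold with the groups separate, the 3 members of each list with the smallest p, up to 12 members of the runs of the highest and lowest window, and 10 genes named in any case, of which 2 had no value here. The first part of this rule was also applied to the fit with the replicate block after the data were examined.

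The labels do not say that equal replicate numbers pair the arrays, and there are only 2 numbers, so the main model had no block. The hybridisation controls differed by replicate number, although the labels do not say whether arrays of the same number were run together. The fit with the replicate number as a block and the values within each number are therefore given as well. Alternatives were other pseudocounts, no filter or only the brightest 25% of probe sets, other normalizations and ways of combining probe sets, tests of every probe set, limma without a trend, a minimum log2 difference of 1, fry in place of camera, other window lengths, the window mean, and leaving out each array in turn, in which the lone array of a group is assumed to vary like the other group.

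The steps were tested on simulated data with the means and spread of the hsr negative arrays, and a wider spread for the hsr positive arrays. That wider spread was set by hand, was smaller than the real one, and genes varied independently. The counts below therefore cannot tell how often genes or lists that move together are called without an effect. Of 50 genes changed at each log2 size in 12334 genes, limma without a block recovered 0 at a size of 1, 8 at 2, 39 at 3 and 47 at 4, and with the block 0, 7, 37 and 43, with 0 false calls. A run of 30 neighbouring genes raised by 1 gave a family-wise permutation p of 0.000999, with 25 of the 30 genes found, and 2 of 40 simulations without an effect had a p under 0.05. Of 10 lists raised by 0.5 all 10 were called, and of 40 unchanged lists 0 were.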

Results

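Gene expression was measured in the human embryonic stem cell line H14 in 2 forms. The hsr positive form, H14 BJI, has an abnormal karyotype with a homogeneously staining region (hsr), a stretch of chromosome that stains evenly and holds amplified genes. The hsr negative form, H14.s3, has a normal karyotype per its labels. Each state came from a single form, so effects of the hsr cannot be told apart from other differences between the forms. Each form was hybridised to 2 Affymetrix arrays, from cells of different passages per the design text, which gives 4 arrays in all and limits the precision of every value below. Nothing in the labels says whether the passages were grown as separate cultures, so limma p-values measure only the spread between these samples. The permutation p of windows and the camera p with the preset correlation set genes against other genes. A small value of these does not show agreement between samples. The median signal was 26.6 and 23.6 on hsr positive replicates 1 and 2, and 23.3 and 24.1 on hsr negative replicates 1 and 2. After filtering, 12334 genes had a value.

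The hsr positive arrays resembled each other less than the hsr negative arrays did. The SD of the log2 difference between replicates was 0.97 in hsr positive cells and 0.50 in hsr negative cells. Across the 12334 genes, which are not independent replicates, the correlation was 0.824 between the hsr positive arrays and 0.954 between the hsr negative arrays, and hsr positive replicate 1 correlated at 0.930 with hsr negative replicate 1. The ratio of the 3' to the 5' beta-actin control signal, a sign of RNA integrity, was 2.78 on hsr positive replicate 2, against 1.06 on hsr positive replicate 1 and 1.56 and 1.34 on hsr negative replicates 1 and 2. The same ratio for GAPDH was 0.981 on hsr positive replicate 2 and 0.921, 1.21 and 0.919 on hsr positive replicate 1 and hsr negative replicates 1 and 2. The hybridisation controls split the arrays by replicate number: the mean bioB signal was 262.1 and 292.7 on the hsr positive and hsr negative arrays of replicate 1, and 105.97 and 112.43 on those of replicate 2. For that reason, values within each replicate number and with the replicate number as a block are given beside the results.

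The first question, posed by the amplification in the sample descriptions, was whether genes that neighbour each other on a chromosome were higher together in hsr positive cells. A run of 69 neighbouring genes of chromosome 17, from MGC12916 to IFT20, had a median log2 difference of 1.53. In it, 59 of the 69 genes were higher in hsr positive cells. The run was delimited by these same differences, so its median and the counts of higher genes in it partly follow from that choice. The increase was concentrated in the middle 53 genes, from PIGL to NATD1, with a median of 1.84 and 43 genes at a log2 difference of 1 or more, whereas the first 8 and last 8 genes had medians of 0.11 and 0.19. PIGL, an enzyme of glycosylphosphatidylinositol anchor synthesis, had a signal of 1933 ± 822 in hsr positive and 59.95 ± 13.5 in hsr negative cells (SD, n = 2 each), a log2 difference of 4.63 ± 0.44 (SE). MPRIP, which binds myosin phosphatase, had a signal of 3376 ± 433 against 532.75 ± 83.5, a log2 difference of 2.63 ± 0.29. ALKBH5, an RNA demethylase, had a signal of 2320 ± 832 against 280.9 ± 1.41, a log2 difference of 2.93 ± 0.37.

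Other members of the run spanned many functions. The log2 difference was 4.42 ± 0.38 (SE) for the non-coding RNA CCDC144NL-AS1, 3.65 ± 0.39 and 3.05 ± 0.55 for the zinc finger genes ZNF287 and ZNF624, and 3.24 ± 0.45 for GID4, part of a ubiquitin ligase. It was 3.05 ± 0.42 for PEMT, a phospholipid methyltransferase, 3.002 ± 0.596 for the GTP-binding protein DRG2, and 2.88 ± 0.53 for FLCN, the folliculin gene mutated in Birt-Hogg-Dubé syndrome. The autophagy kinase ULK2 had a log2 difference of 2.81 ± 0.38 and RAI1, the gene of Smith-Magenis syndrome, of 2.58 ± 0.44. All 12 of these genes were higher in hsr positive cells within both replicate numbers. They were picked as the run members with the largest differences, so this largely follows from the choice.

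The window of 15 genes centred on MPRIP had a median of 2.46, the highest of 11993 windows, with a two-sided family-wise permutation p of 0.000999 against 1000 shuffles of genes over positions, the smallest p these can give. The highest window also lay in the run in replicate 1 alone (2.48, centred on DRC3) and in replicate 2 alone (2.34, centred on MPRIP), both with the same p of 0.000999, and 55 of the 69 genes were higher in both replicates. Singly, 0 of the 69 genes passed an adjusted p of 0.05 in limma without a block and 20 passed with the replicate number as a block. The ends of the run are less certain than its middle, because a window of 15 genes extends past the genes that raise it.

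**Figure D1:**
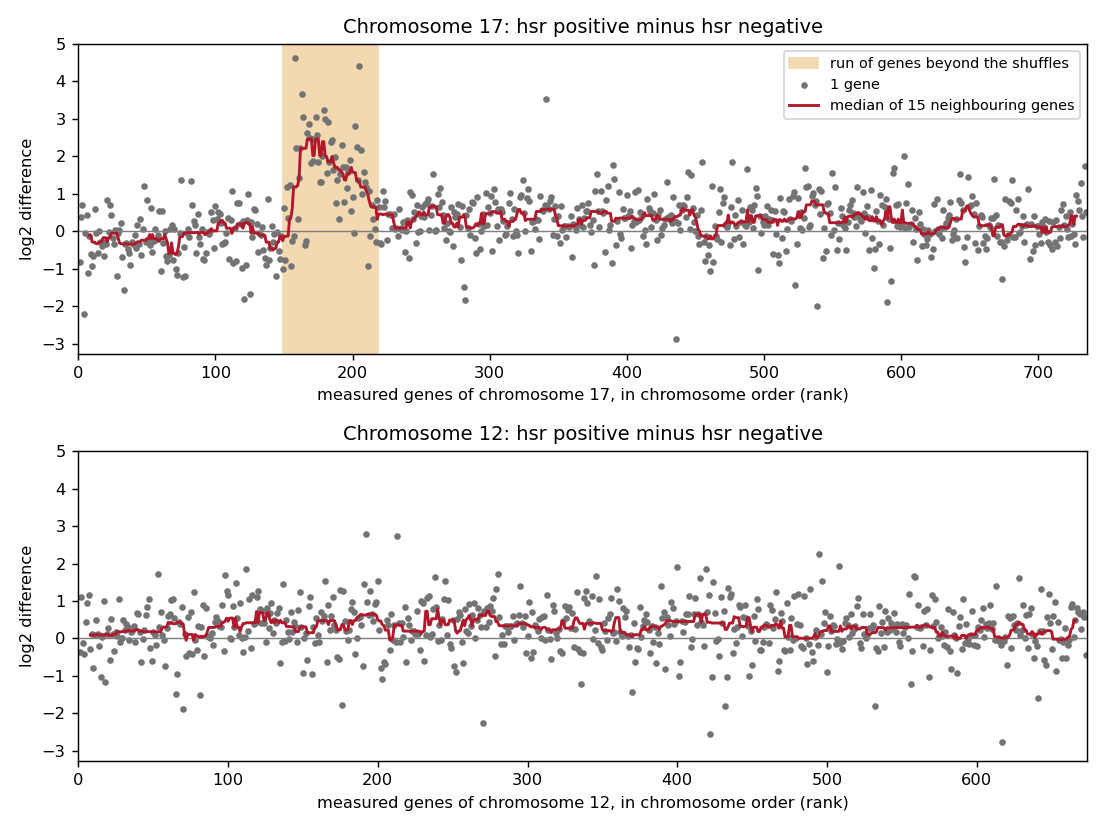
Log2 difference between hsr positive and hsr negative cells for each measured gene of chromosome 17 (upper panel) and chromosome 12 (lower panel), in chromosome order. Points are genes, the line is the median of 15 neighbouring genes, and the shaded run of 69 genes on chromosome 17 reaches a window median of 2.46, while the 673 genes of chromosome 12 have a median of 0.31 along the chromosome.

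**Figure D2:**
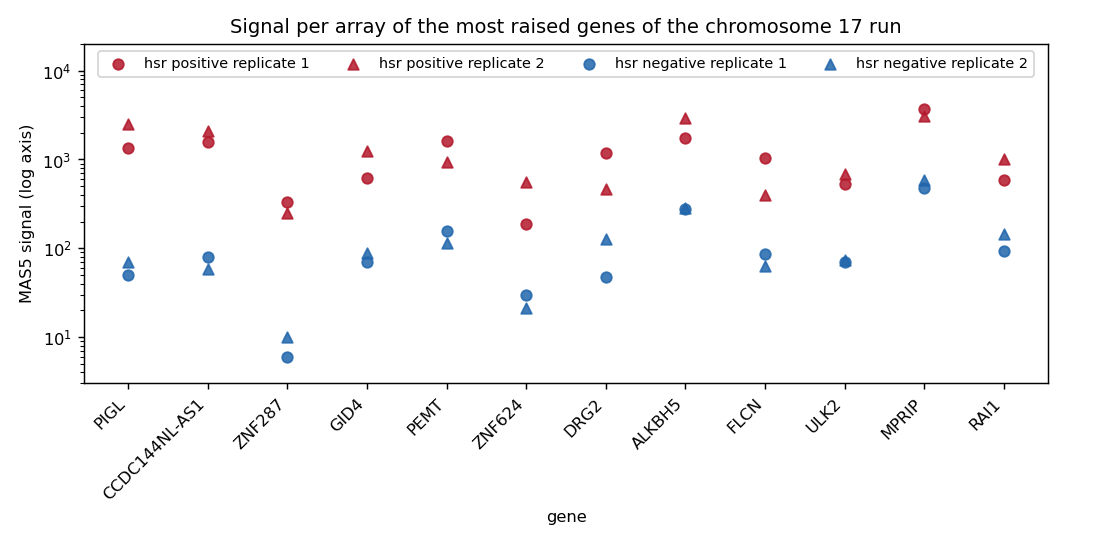
MAS5 signal (log axis) of the 12 genes with the largest difference in the chromosome 17 run, with hsr positive arrays in red and hsr negative arrays in blue, circles for replicate 1 and triangles for replicate 2. Both hsr positive arrays lie above both hsr negative arrays for each gene, as for PIGL with means of 1933 and 59.95.

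At the other extreme, the lowest window was on chromosome 11, centred on TPCN2, with a median log2 difference of -0.90 (family-wise permutation p = 0.0350). It formed a run of 16 genes from PPP6R3 to SHANK2, of which 3 were higher in hsr positive cells. The run included FGF4, a growth factor of pluripotent cells, at -1.74 ± 0.49 (SE), the receptor gene MRGPRF at -1.89 ± 0.49, the cortactin gene CTTN at -0.96 ± 0.35, the mitochondrial ribosomal gene MRPL21 at -0.91 ± 0.40, the death receptor adaptor FADD at -0.90 ± 0.47 and the ion channel gene TPCN2 at -1.0 ± 0.56. Further members were the neuropeptide gene GAL at -1.67 ± 1.12, the cyclin gene CCND1 at -1.09 ± 0.60, the carnitine palmitoyltransferase gene CPT1A at -0.72 ± 0.43, FGF19 at -0.70 ± 0.52, IGHMBP2 at -0.50 ± 0.40 and TESMIN at 0.53 ± 0.42. No gene of this run passed limma with or without the block (0 of 16 each). CTTN was higher rather than lower with the mean of its probe sets. The run's median was -0.09 in replicate 1 and -1.24 in replicate 2, and without hsr positive replicate 1 the lowest window of the genome had a p of 0.288, without hsr negative replicate 2 a p of 0.115. The call was also lost with other pseudocounts, without a filter on dim probe sets, with the mean of a gene's probe sets, with the window mean and with windows of 7 or 31 genes, and in several of these settings the lowest window lay on another chromosome.

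The next question was whether genes of a whole chromosome were shifted. Genes of chromosomes 12 and 17 rose as groups in hsr positive cells. On chromosome 12, 70.7% of 673 genes were higher, with a median log2 difference of 0.31, and the 4 equal parts of the chromosome in gene order had medians of 0.29, 0.37, 0.35 and 0.23. Against the median of -0.09 over the 10926 genes of other chromosomes, the chromosome 12 shift was 0.40 on the log2 scale, or 1.32-fold. On chromosome 17, 67.1% of 735 genes were higher, with a median of 0.24. The 517 genes after the run had a median of 0.28 with 72.9% higher, a shift of 1.30-fold against the other chromosomes, whereas the 149 genes before the run had a median of -0.14 with 38.3% higher.

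The shift was tested with camera, with the preset correlation of 0.01, and the adjusted p was 1.46e-08 for chromosome 12 and 4.97e-08 for chromosome 17. With an estimated correlation the adjusted p was 0.317 for chromosome 12 and 0.727 for chromosome 17, so that neither call held. That test had 2 residual degrees of freedom and could hardly pass any set. With the replicate block the adjusted p was 9.77e-08 and 1.55e-07. The median of chromosome 12 was 0.33 in replicate 1 and 0.26 in replicate 2, and that of chromosome 17 was 0.40 and 0.14. Without a filter on dim probe sets the medians were smaller, 0.19 for chromosome 12 and 0.14 for chromosome 17 (adjusted p = 0.000336 and 0.000358). Chromosome 17 outside the run had medians of 0.35 and 0.06 in replicates 1 and 2. Without the genes of the run, a test added after the data were examined, the other 666 genes of chromosome 17 had a median of 0.18 (camera adjusted p = 0.000157, 0.000567 with the replicate block, and adjusted p = 0.727 with an estimated correlation). Leaving out hsr positive replicate 1 gave these 666 genes a median of 0.10 and an adjusted p of 0.502, and gave all of chromosome 17 a median of 0.16 and an adjusted p of 0.104. Of the other chromosomes none passed, with a smallest adjusted p of 0.744 by camera.

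Among single genes, NLRP2 fell in hsr positive cells. NLRP2, a NOD-like receptor family gene, had a signal of 1.55 ± 1.20 in hsr positive and 634.9 ± 16.7 in hsr negative cells (SD, n = 2 each), a log2 difference of -5.21 ± 0.36 (SE), and the log2 difference was -5.12 in replicate 1 and -5.31 in replicate 2. It was the only gene of 12334 past an adjusted p of 0.05 in limma without a block (adjusted p = 0.0261), and its adjusted p ranged from 0.0541 to 0.0596 where the call was lost, with pseudocounts of 1 and 64, without a filter on dim probe sets and in the brightest 25% of probe sets. When every probe set was tested on its own, 0 of 27270 passed without a block. A further 12 genes just missed the threshold and were not called, at an adjusted p of 0.0502, among them PIGL, CCDC144NL-AS1, ZNF287 and MPRIP of the chromosome 17 run. At an adjusted p of 0.1, 8 genes were higher and 13 lower, and at an unadjusted p of 0.05, 384 were higher and 548 lower. The count of genes past the threshold was 2566 without hsr positive replicate 1, 190 without hsr positive replicate 2, 3 without hsr negative replicate 1 and 2 without hsr negative replicate 2.

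With the replicate number as a block, 31 genes rose and 36 fell at an adjusted p of 0.05, for a total of 67. That fit left 1 residual degree of freedom, against 2 without the block. The spread borrowed from other genes weighed 10.6 degrees of freedom with the block and 4.93 without it. Calls of the block fit therefore rest mainly on borrowed spread. NLRP2 was called by both fits. Of the 31 that rose, 20 lay in the chromosome 17 run of 69 genes, which was itself delimited by the same differences, and of the 36 that fell, 0 lay in it. Outside the run, the genes with the largest rise in this fit were the neural transcription factors ZIC1 (4.09 ± 0.59, SE of the block fit) and NR2F1 (3.83 ± 0.43), the protein kinase inhibitor gene PKIB (3.56 ± 0.42) and the neuronal secreted protein gene LGI1 (3.04 ± 0.48). The adjusted p with the block was 0.00988, 0.00209, 0.00261 and 0.0142 for these. ZIC1 had a signal of 169.5 and 1282 on hsr positive replicates 1 and 2 and of 13.8 and 11.8 on the hsr negative arrays.

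Several of the genes that fell most in the block fit encode proteins of contractile cells. They were the actin-binding protein gene TAGLN (-4.02 ± 0.56), the muscle actins ACTA1 (-3.70 ± 0.52), ACTC1 (-3.53 ± 0.35) and ACTG2 (-3.41 ± 0.46), and the myosin light chain gene MYL7 (-3.79 ± 0.45). ACTC1 had a signal of 264.65 ± 19.9 in hsr positive and 3295 ± 1038 in hsr negative cells (SD, n = 2 each). The endothelin receptor EDNRB (-4.01 ± 0.42), the ferroxidase HEPH (-3.87 ± 0.43), the membrane protein gene ITM2A (-3.82 ± 0.43), the RNA-binding protein gene KHDRBS3 (-3.64 ± 0.44), the calcium-binding protein gene S100A6 (-3.37 ± 0.45) and FAM217B (-3.27 ± 0.41) fell as well. Their largest adjusted p with the block was 0.00799, in ACTA1. Genes outside the run were chosen here by the planned rule applied to the block fit after the data were examined, since the fit without a block called 1 gene.

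Gene lists fixed before the data were examined were tested next, to ask which cell states and pathways differed. Genes of the pluripotent state fell as a group in hsr positive cells, with 29 of 30 measured factors and markers lower and a median log2 difference of -1.02. The chromatin factor JARID2 had a log2 difference of -1.47 ± 0.36 (SE), FGF4 of -1.74 ± 0.49 and the RNA-binding protein gene L1TD1 of -1.61 ± 0.53. DNMT3B, the de novo DNA methyltransferase of stem cells, had a signal of 2941 and 810.5 on hsr positive replicates 1 and 2 and of 4360 and 4239 on the hsr negative arrays, with a log2 difference of -1.46 ± 0.54. The log2 difference was -0.94 ± 0.43 for NANOG and -0.42 ± 0.41 for SOX2. Nodal and TGF-beta targets fell too, with 12 of 12 lower and a median of -0.69, including LEFTY1 (-2.70 ± 1.09), NODAL (-2.41 ± 0.95) and SMAD7 (-1.02 ± 0.38). FGF and ERK targets fell with 17 of 19 lower and a median of -0.73, including FOSL1 (-1.89 ± 0.45), FGF2 (-1.46 ± 0.45) and DUSP4 (-1.07 ± 0.38).

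The camera adjusted p was 2.91e-07 for the pluripotency list, 0.00155 for nodal and TGF-beta targets and 0.000830 for FGF and ERK targets, and with an estimated correlation the adjusted p was 0.649 for each. No member of these lists passed limma over all genes tested, with or without the block, and without it 0 passed when adjusted over the list alone. With the block, LEFTY1 and NODAL were lower over the nodal list alone. Over the FGF and ERK list alone, FGF2 and FOSL1 were lower and EGR1 was higher. The list medians in replicates 1 and 2 were -0.36 and -1.85 for pluripotency, -0.42 and -0.99 for nodal and TGF-beta, and -0.09 and -1.47 for FGF and ERK. The larger fall thus lay in the pair with the beta-actin ratio of 2.78 and the GAPDH ratio of 0.981. The pluripotency median was -0.26 without hsr positive replicate 2 (adjusted p = 0.0450) and -2.01 without hsr positive replicate 1 (adjusted p = 1.01e-15), and that of FGF and ERK targets was -0.25 (adjusted p = 0.254) and -1.12 (adjusted p = 0.000132), with -0.47 without hsr negative replicate 2 and -0.36 with the mean of a gene's probe sets. With the replicate block, the adjusted p was 2.11e-11 for pluripotency, and 11 pluripotency members were lower when adjusted over the list alone; all 13 lists called over the 4 arrays kept their call and direction with the block.

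Markers of the neural lineage rose as a group in hsr positive cells. Of 16 measured neuroectoderm markers, 12 were higher and 4 lower, with a median log2 difference of 1.88 and camera adjusted p of 0.000107 (adjusted p = 0.649 with an estimated correlation). The neural transcription factors ZIC1, SOX1 and PAX3 had log2 differences of 4.09 ± 0.84, 2.11 ± 0.46 and 1.87 ± 0.41 (SE of the fit without a block). Over all genes tested 0 neuroectoderm markers passed limma without a block, and adjusted over the list alone 7 passed as higher and 2 as lower. The neuroectoderm median was 0.84 in replicate 1 and 2.25 in replicate 2, the larger rise in the pair with the beta-actin ratio of 2.78 and the GAPDH ratio of 0.981. Without hsr positive replicate 2 it was 0.40 (adjusted p = 0.0206), and without a filter on dim probe sets it was 0.70 (adjusted p = 0.000227).

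Trophoblast markers, genes of the placental lineage, rose as a group over the 4 arrays but not within both replicates. Of 20 measured, 18 were higher, with a median log2 difference of 1.30, and the transcription factors TFAP2B and TFAP2A had log2 differences of 3.39 ± 0.88 and 3.33 ± 0.84 and the X-linked antigen gene XAGE2 of 2.33 ± 0.53. The camera adjusted p was 0.000437 (adjusted p = 0.649 with an estimated correlation), with 0 markers past limma without a block over all genes tested and 3 higher when adjusted over the list alone. With the block, 3 were higher and 1 lower over the list alone. The trophoblast median was -0.47 in replicate 1 and 2.99 in replicate 2, so that the rise lay only in the pair with the beta-actin ratio of 2.78 and the GAPDH ratio of 0.981. It was -0.40 without hsr positive replicate 2 (adjusted p = 0.280) and 2.82 without hsr positive replicate 1 (adjusted p = 3.60e-14), and 0.83 with pseudocount 64. BMP targets had a median of 0.50 with 10 of 17 higher (camera adjusted p = 0.107), including DLX3 at 1.85 ± 0.61 and HAND1 at -1.002 ± 0.372. They passed without hsr positive replicate 1 (0.69, adjusted p = 0.0150), without hsr negative replicate 1 (0.15, adjusted p = 0.0296) and without hsr negative replicate 2 (0.35, adjusted p = 0.0299), but without hsr positive replicate 2 the median was -0.024 (adjusted p = 0.610).

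Markers of other germ layers did not pass as groups over the 4 arrays. The mesoderm and mesendoderm list had a median of -0.44 with 12 of 19 lower (camera adjusted p = 0.107). Adjusted over the list alone, 1 of its genes was higher and 3 were lower without a block, and 2 were higher and 3 lower with it. ACTC1, the vascular receptor KDR and the growth factor receptor PDGFRA of this list had log2 differences of -3.53 ± 0.35, -2.23 ± 0.45 and -1.80 ± 0.40. The mesoderm list passed as lower without hsr positive replicate 2 (-0.44, adjusted p = 0.00996), without hsr negative replicate 1 (-0.78, adjusted p = 0.00370) and with the mean of a gene's probe sets (-0.44, adjusted p = 0.0238). It did not without hsr positive replicate 1 (-0.43, adjusted p = 0.692) or without hsr negative replicate 2, where its median was -0.034 (adjusted p = 0.705). Endoderm and yolk sac markers had a median of -0.10 with 10 of 20 lower (adjusted p = 0.325), and medians of -0.80 in replicate 1 and 0.87 in replicate 2, and passed as lower without hsr positive replicate 2 (-0.80, adjusted p = 8.90e-06) but not without hsr positive replicate 1 (1.05, adjusted p = 0.0896). GATA4, GATA6 and APOB had log2 differences of -1.64 ± 0.43, -1.28 ± 0.42 and -1.19 ± 0.45. Germ cell genes had a median of -0.27 with 5 of 7 lower (adjusted p = 0.171), and of -0.72 without hsr positive replicate 1 and -0.48 without hsr negative replicate 2, among them TEX14 at -1.43 ± 0.44, TEX15 at -1.27 ± 0.57 and KIT at -0.95 ± 0.41.

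Fibroblast and feeder-like markers fell as a group in hsr positive cells, to a similar extent in each replicate. Of 28 measured, 25 were lower, with a median log2 difference of -1.01 over the 4 arrays, -1.02 in replicate 1 and -1.08 in replicate 2. TAGLN had a log2 difference of -4.02 ± 0.73, S100A6 of -3.37 ± 0.41 and the galectin gene LGALS1 of -2.44 ± 0.45. Cell adhesion and surface genes fell with 25 of 32 lower and a median of -0.33, and of these CD44, the hyaluronan receptor, had a log2 difference of -2.31 ± 0.50, PROM1 of -1.94 ± 0.41 and THY1 of -1.73 ± 0.49. The camera adjusted p was 1.63e-07 for fibroblast markers and 0.00389 for cell adhesion genes, and with an estimated correlation the adjusted p was 0.649 for both. Over all genes tested 0 members passed limma without a block, while adjusted over the list alone 6 fibroblast markers and 2 cell adhesion genes were lower. Without hsr positive replicate 1 the cell adhesion genes had a median of -0.18 and an adjusted p of 0.206.

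Genes of DNA replication, repair and division fell as groups over the 4 arrays, but beyond matched random lists only in replicate 2. All 31 measured G1/S and replication genes were lower, with a median log2 difference of -0.91, and the replication licensing factor CDT1, the flap endonuclease FEN1 and GINS2 had log2 differences of -1.81 ± 0.60, -1.47 ± 0.62 and -1.32 ± 0.53. Of 33 G2/M genes 28 were lower, with a median of -0.47, including the cyclin CCNB1 at -0.95 ± 0.51, HMMR at -0.93 ± 0.51 and the spindle checkpoint kinase TTK at -0.87 ± 0.44. Of 26 DNA repair genes 22 were lower, with a median of -0.49, including the helicase BLM at -1.09 ± 0.57, FANCI at -0.82 ± 0.42 and XRCC6 at -0.50 ± 0.29. The camera adjusted p was 4.28e-07, 0.00947 and 0.0141, and with an estimated correlation the adjusted p was 0.649, 0.693 and 0.649. No member passed limma over all genes tested or adjusted over the list alone (0 in each list). The medians in replicates 1 and 2 were -0.23 and -1.67 for G1/S genes, 0.14 and -1.14 for G2/M genes and -0.21 and -0.64 for DNA repair genes, so that the larger or only fall lay in the pair with the beta-actin ratio of 2.78. Without hsr positive replicate 1 the medians were -1.82 for G1/S, -1.13 for G2/M and -0.85 for DNA repair genes. Without hsr positive replicate 2 they were -0.19 for G1/S genes (adjusted p = 0.523), 0.20 for G2/M genes (adjusted p = 0.0182, in the other direction) and -0.09 for DNA repair genes (adjusted p = 0.843), and DNA repair genes also lost the call without hsr negative replicate 1 (-0.34, adjusted p = 0.146) and with the mean of a gene's probe sets (-0.31, adjusted p = 0.0685).

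Lists of cell death and oncogenes did not pass. Apoptosis and survival genes had a median of -0.19 with 18 of 29 lower (camera adjusted p = 0.259), including CFLAR at -1.38 ± 0.47, BOK at -1.01 ± 0.38 and TNFRSF8, the surface receptor CD30, at -1.86 ± 0.79. The survival gene BCL2L1 had a log2 difference of -0.40 ± 0.38. Targets of p53 had a median of -0.04 with 15 of 27 lower (adjusted p = 0.785), including AEN at -1.22 ± 0.44, TP53I3 at -1.10 ± 0.61 and FAS at -0.73 ± 0.42, and MDM2 had a log2 difference of -0.09 ± 0.33. Oncogenes known from amplicons had a median of -0.26 with 22 of 33 lower (adjusted p = 0.167), and medians of -0.50 without hsr positive replicate 1 and 0.016 without hsr positive replicate 2, led by PDGFRA, KIT and SKP2, the last at -0.88 ± 0.38. The log2 difference was -1.13 ± 0.77 for MYC and -0.65 ± 0.47 for MYCN.

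Among stress and signalling lists, hypoxia targets and immediate early genes rose as groups. Of 23 hypoxia targets 18 were higher, with a median log2 difference of 0.82, including TXNIP at 3.08 ± 0.97, DDIT4 at 2.53 ± 0.59 and the mitophagy receptor BNIP3 at 1.00 ± 0.36. Of 18 immediate early genes 15 were higher, with a median of 0.70, including NR4A1 at 1.54 ± 0.69 and ZFP36, which destabilises messenger RNA, at 1.22 ± 0.38, whereas FOSL1 was at -1.89 ± 0.45. The camera adjusted p was 0.000326 for hypoxia targets and 0.00513 for immediate early genes, with an adjusted p of 0.649 for both with an estimated correlation. Without a block 0 members passed limma over all genes tested or adjusted over the list alone. With the block DDIT4 passed limma over all genes tested (adjusted p = 0.0395). Over the list alone, the block fit had 3 hypoxia targets higher and 1 lower, and 4 immediate early genes higher and 1 lower. Hypoxia targets had medians of 0.04 and 1.63 in replicates 1 and 2, with nearly all of the rise in the pair with the beta-actin ratio of 2.78 and the GAPDH ratio of 0.981. They had a median of -0.07 without hsr positive replicate 2 (adjusted p = 0.843) and a median of 1.83 without hsr positive replicate 1. Immediate early genes had medians of 0.91 and 0.71, and lost the call without hsr positive replicate 1 (0.45, adjusted p = 0.337) and in the brightest 25% of probe sets (0.55, adjusted p = 0.0528).

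Imprinted genes, expressed from a single parental copy, rose as a group with members in both directions. Of 21 measured, 16 were higher, with a median log2 difference of 0.45, and NAP1L5 and NNAT were higher at 2.89 ± 0.42 and 2.11 ± 0.39 while PEG3 was lower at -2.51 ± 0.42. PEG3 had a signal of 2.20 ± 1.13 in hsr positive and 88.2 ± 16.8 in hsr negative cells, and NAP1L5 of 165.35 ± 51.4 and 8.10 ± 3.11 (SD, n = 2 each). The camera adjusted p was 0.00437 (adjusted p = 0.649 with an estimated correlation), with 0 genes past limma without a block over all genes tested, and with 2 higher and 1 lower when adjusted over the list alone. With the block NAP1L5 passed limma over all genes tested (adjusted p = 0.0133). The imprinted median was 0.18 in replicate 1 and 0.82 in replicate 2, the larger rise in the pair with the beta-actin ratio of 2.78 and the GAPDH ratio of 0.981. Without hsr positive replicate 1 it was 0.78, and the call was lost without hsr positive replicate 2 (0.19, adjusted p = 0.655) and in the brightest 25% of probe sets (0.14, adjusted p = 0.271).

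Lists of metabolism, protein synthesis, chromatin and WNT signalling did not pass by camera over the 4 arrays. Oxidative phosphorylation genes had a median of -0.23 with 28 of 34 lower (adjusted p = 0.0506), including UQCRC1 at -0.67 ± 0.32, SDHC at -0.64 ± 0.39 and NDUFS3 at -0.59 ± 0.32. This list lay at the threshold, and passed as lower with pseudocount 64 (adjusted p = 0.0449), without a filter on dim probe sets (0.0211), with median centring (0.0329), with the mean of a gene's probe sets (0.0347) and without hsr negative replicate 2 (0.0131). It did not with quantile normalization (-0.10, adjusted p = 0.509), without hsr negative replicate 1 (-0.091, adjusted p = 0.562), without hsr positive replicate 1 (0.206), without hsr positive replicate 2 (0.130), in the brightest 25% of probe sets (0.141) or with the replicate block (0.0681). Glycolysis genes had a median of 0.01 with 11 of 21 higher (adjusted p = 0.785), with ENO2 at 1.74 ± 0.42, HK1 at -0.92 ± 0.34 and ENO1 at -0.51 ± 0.21. Ribosomal protein genes had a median of -0.04 with 21 of 35 lower (adjusted p = 0.947), with RPLP2 at 0.46 ± 0.40, RPL6 at 0.18 ± 0.18 and RPL35 at -0.16 ± 0.19. Heat shock and unfolded protein response genes had a median of -0.11 with 17 of 26 lower (adjusted p = 0.259), and of -0.22 without hsr positive replicate 2, including SDF2L1 at -1.06 ± 0.38, PDIA4 at -0.995 ± 0.346 and HSPA5 at -0.55 ± 0.22. DNA and histone methylation enzymes had a median of -0.28 with 20 of 29 lower (adjusted p = 0.325), led by JARID2, DNMT3A at -1.21 ± 0.44 and SUZ12 at 0.99 ± 0.35. WNT targets had a median of -0.37 with 12 of 18 lower (adjusted p = 0.325), and medians of 0.29 and -1.16 in replicates 1 and 2, with TNFRSF19 at 1.21 ± 0.49, CCND1 at -1.09 ± 0.60 and FRZB at -0.94 ± 0.37. They passed as lower without hsr positive replicate 1 (-0.88, adjusted p = 0.0203) and without hsr negative replicate 1 (-0.53, adjusted p = 0.0434), but had medians of 0.19 (adjusted p = 0.280) without hsr positive replicate 2 and 0.11 (adjusted p = 0.705) without hsr negative replicate 2.

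The short lists of genes from regions often gained in cultured stem cells did not pass over the 4 arrays. They cover only some genes of each chromosome. All measured genes of chromosome 12 had a median log2 difference of 0.31, and those of chromosome 17 of 0.24. Genes of chromosome 12p had a median log2 difference of 0.11 with 13 of 19 higher (camera adjusted p = 0.167), and ranged from the cell cycle inhibitor CDKN1B at 1.69 ± 0.41 to GDF3, a pluripotency-associated growth factor, at -1.47 ± 0.70. Genes of chromosome 17q had a median of 0.06 with 13 of 23 higher (adjusted p = 0.258), from HOXB2 at 1.86 ± 0.61 and SOX9 at 1.70 ± 0.59 to NME1 at -1.04 ± 0.41. Genes of band 20q11.21 had a median of 0.00 with 9 of 18 higher (adjusted p = 0.813), with ID1 at 0.50 ± 0.25 and COMMD7 at -0.81 ± 0.35. The medians in replicates 1 and 2 were 0.50 and -0.31 for the 12p list, 0.47 and -0.05 for the 17q list and 0.16 and -0.20 for the 20q11.21 list. Without hsr positive replicate 2 the 12p list (0.37, adjusted p = 0.00201) and the 17q list (0.49, adjusted p = 0.000121) passed as higher, whereas without hsr positive replicate 1 they were at -0.069 (adjusted p = 0.724) and -0.19 (adjusted p = 0.409). Adjusted over the list alone without a block, 0 genes passed in each of these and in every other list that camera did not call, except mesoderm. With the block, CDKN1B of the 12p list and HOXB2 of the 17q list passed as higher and DNMT3B of the 20q11.21 list as lower. ENO2 of glycolysis and TFAP2A of the BMP targets passed as higher there too. PDGFRA of the oncogenes and DNMT3B and JARID2 of the methylation enzymes passed as lower.

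**Figure D3:**
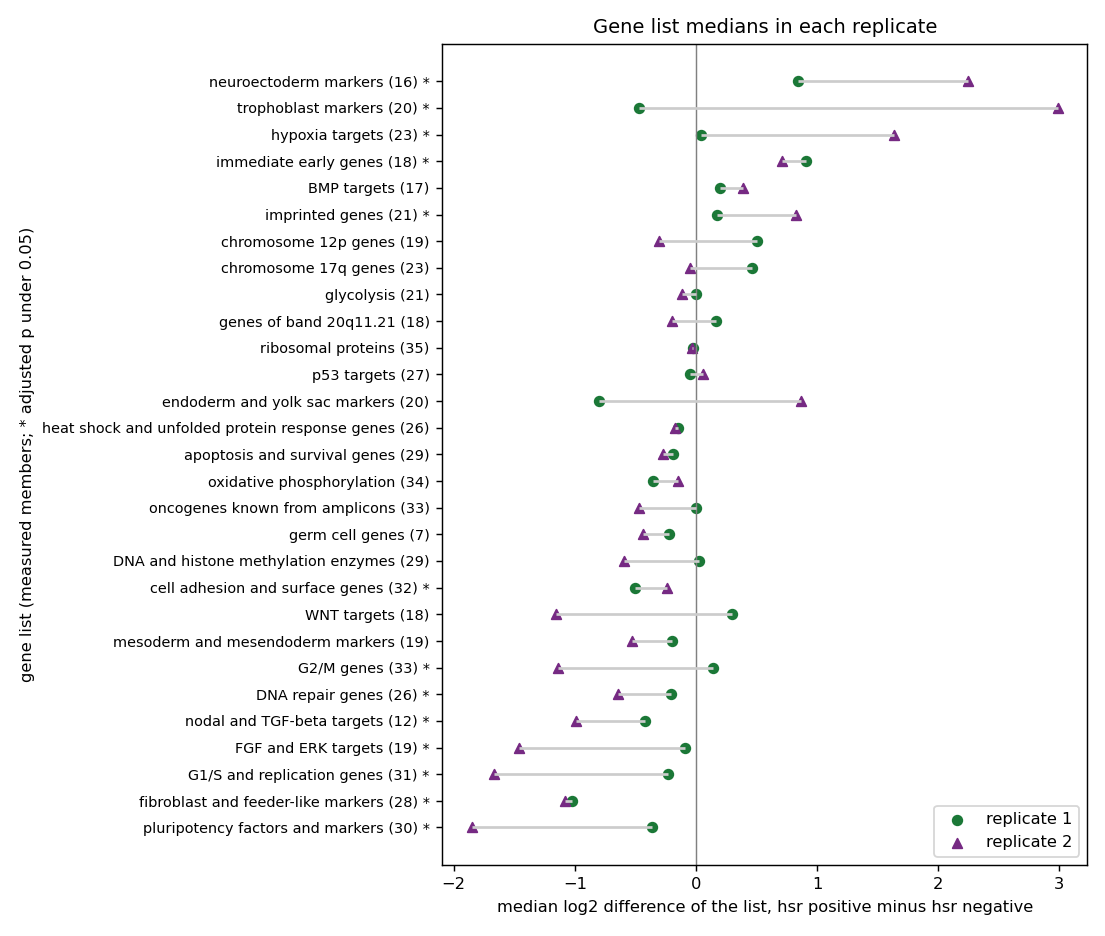
Median log2 difference of each of the 29 gene lists within replicate 1 (circles) and replicate 2 (triangles), with the number of measured members in brackets and an asterisk for the 13 lists with a camera adjusted p under 0.05. The fibroblast list lies at -1.02 and -1.08, the pluripotency list at -0.36 and -1.85 and the trophoblast list at -0.47 and 2.99.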

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

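The test of every probe set with the replicate number as a block was added after the data were examined. In it, 11 of 4568 probe sets that the annotation pairs with no gene or with several, and that the gene comparisons therefore left out, passed an adjusted p of 0.05 in limma, 7 higher and 4 lower in hsr positive cells. Without the block 0 of them passed, and of all 27270 probe sets tested 91 passed with the block and 0 without it. Probe set 227963_at had a signal of 448.8 and 1502 on the hsr positive arrays and of 5 and 6.7 on the hsr negative arrays, a log2 difference of 5.27. Probe set 225065_x_at had a log2 difference of 3.09, 224646_x_at of -4.44 and 226192_at of -2.85. They are unnamed here, so their place on the chromosomes was not examined.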

How the results depend on the processing

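The test of every probe set with the replicate number as a block was chosen after the data were examined. The highest window stayed on chromosome 17 with a permutation p of 0.000999 in every setting run. Of the 13 lists called, 13 kept call and direction with pseudocounts of 1 and 64, without a filter, with quantile normalization, with median centring and with the replicate block, 11 in the brightest 25% of probe sets and 12 with the mean of a gene's probe sets. With an array left out, 11 did without hsr positive replicate 1, 12 without hsr negative replicate 1 and 13 without hsr negative replicate 2, but without hsr positive replicate 2 only 6 did, while 4 lost the call and 3 turned (trophoblast, G2/M and hypoxia).

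The correlation of deviations between arrays of the same replicate number was 0.178, and the number is not taken as pairing the arrays. The gene count of 1 was 67 with the replicate block and 91 for every probe set with the replicate block. It was 13 with quantile normalization, 13 with median centring and 12 with the mean of a gene's probe sets, and 0 with pseudocount 1, pseudocount 64, no filter, the brightest 25% of probe sets or every probe set. Leaving out an array gave 2 to 2566 genes: 2566 without hsr positive replicate 1, 190 without hsr positive replicate 2, 3 without hsr negative replicate 1 and 2 without hsr negative replicate 2. The number of genes tested, the residual degrees of freedom with the block and the spread of a lone array differ by construction. Otherwise the cause was not tested. Of genes at an unadjusted p of 0.05, 41.2% were higher as deposited and 31.8% with median centring, and the median of all genes was -0.06 and -0.11.

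The 13 list calls were 0 with an estimated correlation and 0 with fry, which called 1 list at an unadjusted p of 0.05, and 11 to 15 lists were called with an array left out, which were not all the same lists. The 2 chromosome calls were 0 with an estimated correlation, where the medians of 0.31 and 0.24 did not pass, and 1 to 2 with an array left out. The median of chromosome 17 was 0.16 to 0.36 with an array left out, and without a filter the medians of chromosomes 12 and 17 were 0.19 and 0.14. The lowest window had a median of -1.09 with 7 genes, -0.54 with 31, -0.78 with the window mean, -0.94 with pseudocount 1, -0.61 with pseudocount 64, -0.72 without a filter, -0.69 with the mean of probe sets and -1.15 to -0.88 with an array left out, and in these its p ranged from 0.115 to 0.762 where the call was lost. It left chromosome 11 with 31 genes, the mean of probe sets and without hsr negative replicate 2 (chromosome 7), with pseudocount 64 (chromosome 5), without a filter (chromosome 1) and without hsr positive replicate 2 (chromosome 16, -0.95, permutation p = 0.00200). The replicate SDs of hsr positive and hsr negative cells were 1.22 and 0.67 with pseudocount 1, and 0.85 and 0.52 without a filter.

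The direction of the test turned, with the median on the same side of 0, for the 20q11.21 list with fry (0.00189) and for p53 targets (-0.028) and ribosomal proteins (-0.036) in the brightest 25% of probe sets. With an array left out the same was seen, among others, for p53 targets without hsr positive replicate 1 (-0.025) and the 20q11.21 list without hsr negative replicate 1 (0.026). Log2 differences themselves turned in others. Ribosomal proteins were at 0.00312 with quantile normalization and 0.042 with the mean of probe sets. Endoderm was at 0.16 without a filter and 0.00714 with pseudocount 64, and glycolysis at -0.044 with median centring and -0.035 with the mean of probe sets. The 20q11.21 list, at 0.00189, was below 0 with pseudocount 1, quantile normalization, median centring and in the brightest 25% of probe sets. CTTN was at 0.58 and BCL2L1 at 0.069 with the mean of probe sets. With an array left out, medians ranged from -0.80 to 1.05 for endoderm, -0.40 to 2.82 for trophoblast, -0.27 to 0.051 for p53 targets, -0.28 to 0.24 for 20q11.21, -0.069 to 0.37 for 12p, -0.19 to 0.49 for 17q, -1.13 to 0.20 for G2/M, -0.070 to 0.00150 for ribosomal proteins, -0.083 to 0.15 for glycolysis, -0.069 to 1.83 for hypoxia, -0.88 to 0.19 for WNT, -0.024 to 0.69 for BMP, -0.50 to 0.016 for amplicon oncogenes and -0.59 to 0.023 for methylation enzymes. Without turning, they ranged from -0.72 to -0.24 for germ cell genes and -0.22 to -0.14 for heat shock genes. For single genes they ranged from -3.70 to 0.37 for GAL, -0.93 to 0.090 for SOX2, -2.40 to 0.15 for MYC and -0.20 to 0.026 for MDM2.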

Other observations

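The tests of the changes in hsr positive replicate 2, the HOX and contractile lists, the probe type values of the chromosome 17 run and all values within a replicate number were chosen after the results they follow were seen. Genes of contractile cells were lower in hsr positive cells beyond those already named. A list of 35 smooth and cardiac muscle genes, which left out the genes already called and shared 1 gene with the fibroblast list, had 22 measured members, of which 18 were lower, with a median log2 difference of -0.68. The camera test of limma gave this list an unadjusted p of 1.16e-06 with the preset correlation and of 0.0778 with an estimated correlation, and the list was drawn up after contractile genes had been seen to fall. The vinculin gene VCL had a log2 difference of -1.46 ± 0.37 (SE), caldesmon CALD1 of -1.14 ± 0.29, tropomyosin TPM2 of -2.05 ± 0.60, cardiac troponin TNNC1 of -2.12 ± 0.53 and titin TTN of -1.70 ± 0.40, and none passed limma over all genes. The most abundant members, MYL6 and TPM1, had log2 differences of -0.36 ± 0.21 and -0.56 ± 0.27. The list lay at -0.50 in replicate 1 and -1.02 in replicate 2, each at percentile 0 of matched random lists. A candidate explanation is fewer contractile, mesenchyme-like cells in both hsr positive cultures. The list was drawn up after such genes had been seen to fall, so its values restate the pattern and cannot decide on a cause. They cannot tell fewer such cells from lower expression of these genes within the cells. No technical explanation was tested for the pattern.

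Genes of chromosome 17 that lie together were higher in hsr positive cells. Lower RNA quality of hsr positive replicate 2 is argued against by replicate 1 alone, where the highest window was 2.48. Cross-hybridisation limited to probe sets with a suffix for shared sequence is argued against by the 42 run genes without one. Their median was 1.45, close to the 1.53 of the 27 with a suffix. The run was delimited by these same differences, so only the likeness of the medians bears on this, not their height. The amplification named in the sample descriptions may therefore be the source of the run, as a hypothesis, since no copy number was measured here.

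Genes of chromosome 12, and of chromosome 17 outside the run, had medians above 0 by a smaller amount, except the 149 genes of chromosome 17 before the run at -0.14. Lower RNA quality of hsr positive replicate 2 is argued against by replicate 1 alone, where both medians lay at percentile 100 of matched random lists, 0.33 for chromosome 12 and 0.35 for chromosome 17 outside the run; in replicate 2 they were 0.26 and 0.06. A shift of 1.32-fold for chromosome 12 and 1.30-fold for the genes after the run is consistent with an extra copy of these parts in some or all cells, which was not tested. The size of the shift depends on the filter, as without it the medians were 0.19 for chromosome 12 and 0.14 for chromosome 17. The camera calls did not hold with an estimated correlation, a test that 2 residual degrees of freedom left with little power.

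Mostly in hsr positive replicate 2, pluripotency genes were lower and neuroectoderm genes higher, and other lists moved as far between the hsr positive arrays: replicate 2 minus replicate 1 was -1.71 for pluripotency and -1.61 for G1/S genes, and 1.20 for neuroectoderm, 2.93 for trophoblast, 1.84 for endoderm and 1.98 for hypoxia. An array of another cell line is argued against by the chromosome 17 window of 2.34 in replicate 2 alone. Lower RNA quality of that array stays open, because its 3' to 5' ratio was above those of the other 3 arrays for beta-actin (2.78) but not for GAPDH (0.981). More differentiated cells in that culture stay open as well: the HOX genes, mostly silent in pluripotent cells and in no other list here, had a median of 0.35 over 7 measured of 37, at percentile 84.5 of matched random lists. That test cannot decide, because matched lists of so few genes spanned -0.75 to 0.83. The measured genes were also all HOXB or HOXC genes, of chromosomes 17 and 12. Between the hsr positive arrays these chromosomes themselves moved, by -0.21 outside the run and by -0.13. A difference between H14 BJI and H14.s3 may also contribute, as replicate 1 had smaller shifts of -0.36 for pluripotency and 0.84 for neuroectoderm. Whether the hsr itself is the source cannot be told, because each state came from a single form. This was not tested further.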
